A study of Mus musculus with 12 samples.

How the data were processed

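Total RNA of mouse pancreatic islets was sequenced on an Illumina NovaSeq in 12 libraries, 3 in each of 4 groups, and the groups were taken from the sample titles, which write PTPN2 +/+ for the controls and PTPN2 -/- for the islets called bKO in the protocols. Islets were untreated or kept with 3 cytokines (TNF-alpha, IL-1beta and IFN-gamma) for 24 h. Controls carry the genotype label fl/fl. Each treated library has a replicate number from 1 to 3 in its title and from 4 to 6 in its description, and the titles' numbers are used. Per the labels' protocols, the islets of each genotype came from 3 mice. Counts per gene were deposited by the authors as raw whole numbers, for 55536 genes in a full table and for 26532 of these genes, with the same values, in a filtered one, which holds genes with a total of 10 or more. Per the submitters' processing notes, FastQC 0.11.7, cutadapt 1.16, STAR 2.5.2a, featureCounts 1.6.2 and the GRCm38 genome were used, with DESeq2 1.30.0 also named. The annotation release and the strand used in counting are not given in the sources used here, so reads of overlapping genes and of close copies are uncertain. The size factors that came with the sample table were not used.

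From the full table, genes were kept by the filterByExpr function, which left 19800. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood test, a coefficient for each group over all 12 libraries and Benjamini-Hochberg adjustment at 0.05. The comparisons were cytokine against untreated within each genotype, labelled-bKO against control within each treatment, and the difference between the 2 cytokine responses. Levels are counts relative to the scaled library size (CPM), and values of a group are the mean with SD of 3 libraries. The principal component analysis used the 2000 most variable genes. Gene names and positions are from GENCODE release M21, which holds 19794 of the tested genes. Libraries of a group were compared by a chi-square test of their counts over genes with at least 20 counts, and the smallest value per degree of freedom over 12 pairs was 15, far above sampling noise, so no library was counted as a copy of another.

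The tests, 23 gene lists and 12 cell marker lists, and the rule for naming genes were fixed before the data were examined. The lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01 and with a correlation estimated from the data, and with fry; lists of under 3 measured genes were not tested. Called members are counted over all genes and, where said, adjusted over the list alone. The genes named are, in each comparison of 2 groups, up to 8 per direction with the largest change among those at adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between the groups, leaving out predicted genes and pseudogenes. For the difference in response they are the 6 of each sign with the smallest adjusted p, and in every comparison up to 4 members of each list with the smallest adjusted p. Ptpn2, Ins1, Ins2, Gcg, Sst, Ppy, Iapp, Socs1, Nos2, Cxcl10 and Tph1 were always included. Some genes that the rule names are not reported here. Genes of a list with a group at 0 to 3 counts are not named. A gene named in 1 comparison is also given in others.

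Libraries hold 54460375 to 77582270 counts in untreated and 52930884 to 107515565 in treated control islets, and 59411699 to 62955944 in untreated and 47064061 to 57223340 in treated islets labelled bKO. The test was tried on simulated data, counts drawn with the means, spreads and library sizes found here and with changes planted in 200 genes. The other genes were drawn without the effect under test, whereas most genes changed with cytokines in the real data. The shares found are therefore not the power of the real cytokine comparisons, and for the others they depend on how many genes truly change. The test found 2-fold changes in 47.7%, 53.8%, 62.5%, 52.2% and 50.7% of genes and 4-fold changes in 83.3%, 85.9%, 95.4%, 89.1% and 74.2%, for the 5 comparisons in the order above. Of its calls 8 of 105, 3 of 112, 3 of 122, 8 of 118 and 4 of 90 were false. DESeq2 made 27 false calls among 131 for the difference in response and 30 among 154 for genotype with cytokines.

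Alternatives were DESeq2's size factors, library totals alone, TMM without acinar markers and without genes over 1% of the counts, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the compared groups only, robust dispersions, stricter thresholds, the filtered table, a replicate block, and leaving out each library in turn. No per-sample column of counts was left unused.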

Results

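Pancreatic islets are clusters of hormone-secreting cells in which the insulin-producing beta cells are the most numerous. Ptpn2 encodes a tyrosine phosphatase that removes phosphate from JAK and STAT proteins, the relays of cytokine signals, and variants near the human gene are linked to type 1 diabetes. The libraries examined here are total RNA of islets from 16-week-old mice, 3 labelled as controls and 3 labelled Ptpn2-bKO, which is read here as a knockout in beta cells. For each genotype, 3 libraries are of untreated islets and 3 are of islets kept for 24 h with TNF-alpha, IL-1beta and IFN-gamma, the cytokines of inflamed islets. Per the protocols the 6 libraries of a genotype come from 3 mice, so some of them must share mice, and which ones is not given. The main tests treat all 12 libraries as independent. Libraries held 47064061 to 107515565 counts. Ins1 and Ins2 together took 12.6% of the counts in untreated control libraries (SD 0.35, n = 3), 13.7% in treated control libraries, 12.7% in untreated libraries labelled bKO and 11.6% in treated ones. The first principal component held 85.5% of the variance and separated treated from untreated libraries. The second held 4.25%, and replicate 2 of the treated islets labelled bKO lay at its end.

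Ptpn2 RNA was not lower in the islets labelled bKO. Untreated islets had 31 CPM (SD 0.63, n = 3) in controls and 35.3 (SD 1.5, n = 3) in those labelled bKO, a log2 difference of 0.19 (SE 0.098, adjusted p = 0.989, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With cytokines the means were 85.9 (SD 6.6) and 101 (SD 14), a log2 difference of 0.23 (SE 0.097, adjusted p = 0.26). Cytokines raised Ptpn2 in both genotypes, by log2 1.47 (SE 0.099, adjusted p = 2.9e-07) in controls and 1.51 (SE 0.10, adjusted p = 2.1e-07) in islets labelled bKO. IFN-gamma and other JAK-STAT signals are known to raise this gene, which acts back on the same pathway. Counts over a whole gene do not test excision of an exon: RNA lacking the excised exon can still be counted, islet cells other than beta cells keep the gene, and the floxed exon is not given in the sources used here. The genotype is therefore written as a label throughout.

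**Figure D1:**
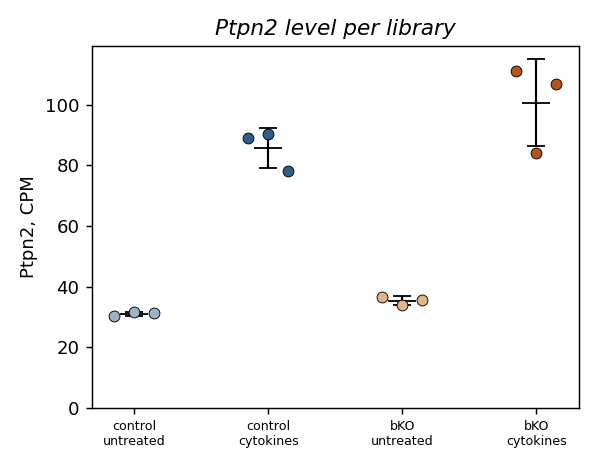
Ptpn2 in CPM (vertical axis) in the 4 groups (horizontal axis). Points are libraries and bars the mean with SD of 3 libraries, 31 and 35.3 in untreated and 85.9 and 101 in treated control and labelled-bKO islets.

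In control islets, cytokines raised all 44 measured interferon target genes, with a median log2 fold change of 4.41. Cxcl9, a chemokine induced by IFN-gamma, went from 0.131 CPM (SD 0.061, n = 3) to 2010 (SD 380), log2 13.85 (SE 0.52, adjusted p = 2.4e-09). Cxcl10 rose 391-fold (log2 8.61, SE 0.22, adjusted p = 2.0e-10), Gbp6, of a family of close copies, by log2 7.53 (SE 0.16), and Irf1 13.4-fold (log2 3.75, SE 0.091). Cd274, the checkpoint ligand PD-L1, rose 39.9-fold, from 21.7 CPM (SD 0.73) to 865 (SD 28). All 37 NF-kB targets and chemokines rose (median 3.09), among them Icam1 (log2 5.61, SE 0.13), Tnfaip3 (4.46, SE 0.091), Cxcl1 (7.66, SE 0.22) and Fas (3.97, SE 0.10). Nos2, whose product makes the nitric oxide through which IL-1beta harms rodent beta cells, rose from 0.294 CPM (SD 0.22) to 1150 (SD 39), log2 11.84 (SE 0.36, adjusted p = 6.0e-10). Antigen presentation rose across class I (23 of 23 genes, median 3.02, with Psmb9 at 4.13, SE 0.10, and Tap2 at 3.06, SE 0.074) and class II (11 of 11, median 2.96, with Cd74 at 3.38, SE 0.20, and Ciita at 6.20, SE 0.35), the second normally a property of immune cells. Of 36 JAK-STAT components and feedback genes, 17 rose and 5 fell, with Socs1, a feedback inhibitor, at log2 5.20 (SE 0.16), Jak2 at 1.68 and Ifngr2 at 1.57. Of 14 STAT5, growth hormone and prolactin targets, 4 rose (Gbp8 6.42, Tnfrsf11b 3.08) and 7 fell (Ehhadh -1.03). Macrophage markers moved with these groups (13 of 15 higher and 1 lower, median 1.12, with C1qa at 1.76, SE 0.13, from 40.4 to 137 CPM, and Cd68 at 1.97), so some of the inflammatory RNA can come from resident immune cells. T cell markers (1 of 4 higher, 2 lower; Lck 1.36, Trac -2.38) and B cell markers (1 of 5 higher, 1 lower; Pax5 3.2, Cd79a -0.86) went both ways. The interferon, class I and NF-kB lists passed the camera test (adjusted p = 6.7e-117, 2.4e-48 and 7.6e-69; adjusted p = 2.3e-04, 1.8e-04 and 1.8e-04 with an estimated correlation). So did class II (1.3e-09; adjusted p = 0.0472 with an estimated correlation) and the JAK-STAT list (2.0e-04; adjusted p = 0.0345 with an estimated correlation), but not the STAT5 list (0.915).

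The same treatment lowered 22 of 30 beta cell identity genes in control islets and raised 0, with a median log2 fold change of -1.50. The transcription factor Pdx1 fell 6.27-fold, from 142 CPM (SD 20, n = 3) to 22.6 (SD 0.31), log2 -2.65 (SE 0.11, adjusted p = 4.1e-09). Ucn3, a marker of mature beta cells, went from 221 CPM (SD 14) to 21.1 (SD 3.3), 10.5-fold lower (log2 -3.39, SE 0.20, adjusted p = 1.0e-07). Isl1 (-1.80, SE 0.13), Prlr (-2.62, SE 0.19) and G6pc2 (-2.17, SE 0.18) fell as well, whereas the hormone genes did not: Ins1 was at 0.15 (adjusted p = 0.533), Ins2 at 0.46 (0.0624) and Iapp at 0.13 (0.609). Ins1 and Ins2 are close copies whose reads are hard to tell apart. A lower Pdx1 is known from cytokine-treated rodent islets. Among 31 exocytosis and granule genes, 8 rose and 12 fell, including Rab3a (-1.62, SE 0.12), Rab27a (-1.66, SE 0.13) and Cacna1d (-1.64). Of 22 genes normally repressed in mature beta cells or active in progenitors, 8 rose (Hk2 2.61, and Nfkb2 2.35, which is also in the NF-kB list) and 4 fell (among them Neurog3, -4.12). Other endocrine cells lost transcripts too: 8 of 9 alpha cell markers (median -1.83; Gcg -1.07, SE 0.15, from 19400 to 9250 CPM), 6 of 6 delta cell markers (-1.39; Sst -1.64, SE 0.20) and 2 of 4 PP cell markers (-1.49; Pyy -2.48, SE 0.14), with 1 of the 4 higher. Adjusted over the list alone, 9 alpha, 3 PP and 22 beta cell genes were lower. Endothelial markers fell in 13 of 13 genes (median -2.23; Kdr -2.92, SE 0.14) and acinar markers in 17 of 19 (-2.27; Cela1 -4.08, SE 0.37), both red blood cell genes fell (-2.70), and ductal (3 higher and 5 lower of 12; Cldn4 1.27), stellate (2 and 1 of 12; Dcn 1.75) and Schwann cell markers (3 and 2 of 8; Ngfr 1.38) were mixed. The fall thus covered endocrine, endothelial, acinar and red blood cell markers but not those of macrophages. Altered cell survival and altered transcription could each produce such a fall in bulk RNA. The beta cell list passed camera (adjusted p = 1.3e-09) but not once its genes' correlation was estimated (adjusted p = 0.353 with an estimated correlation). The alpha (4.9e-06; adjusted p = 0.0765 with an estimated correlation), delta (0.0039; adjusted p = 0.22 with an estimated correlation) and PP lists (0.00815; adjusted p = 0.14 with an estimated correlation) were lost the same way. So were the endothelial (9.5e-11; adjusted p = 0.123 with an estimated correlation), acinar (2.9e-04; adjusted p = 0.63 with an estimated correlation) and macrophage lists (0.00135; adjusted p = 0.485 with an estimated correlation). The fry test, which asks whether the genes of a list changed at all, kept all 21 lists that camera called in controls. Since 60.6% of all tested genes were called, fry does not set these lists apart from other genes.

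Among the stress and death genes of control islets, more rose than fell with cytokines. Ddit3, the CHOP factor of the unfolded protein response, went from 16.2 to 207 CPM (log2 3.67, SE 0.24), and Atf3 from 8.13 to 103 (3.67, SE 0.13), and of 30 ER stress genes 18 rose and 2 fell (median 0.43). Of 36 apoptosis and cell death genes 23 rose and 4 fell (0.87, with Mlkl at 3.62 and Birc3 at 3.58), and of 25 antioxidant genes 22 rose and 1 fell (1.22), led in abundance by Sod2 (3.09, SE 0.094, from 77.4 to 657 CPM). The apoptosis list also holds inhibitors of cell death, such as Birc3. Birc3, Fas and Sod2 stand in the NF-kB list as well, so these lists are not separate from it. Immediate early and handling genes rose in 17 of 24 and fell in 3 (0.94; Klf6 1.55, and the near-identical Hspa1a 5.69 and Hspa1b 5.05), and 24 of 29 cell cycle genes fell and 1 rose (-1.10; Ccnd1 -1.27, SE 0.20; E2f1 -1.10). The glucose transporter Slc2a1 rose from 70.5 to 400 CPM (2.5, SE 0.16) with Pfkfb3 (2.29) and Hif1a (0.98), and 19 of 28 glycolysis genes rose and 6 fell (0.50, with Pfkm at -0.94). Pentose phosphate, serine and amino acid genes rose in 15 of 27 and fell in 5 (0.55, with Arg2 4.09, Pgd 1.6, Mthfd1 -1.12). Of 13 genes encoded in the mitochondrion 8 fell and 1 rose (-1.19; mt-Nd1 -1.71, SE 0.14, from 2440 to 746 CPM; mt-Nd2 -1.80), and of 71 nuclear oxidative phosphorylation genes 31 rose and 8 fell (0.15; Cox7b 0.70, Ndufs1 -0.46). TCA cycle and pyruvate entry genes went both ways (12 of 32 higher, 7 lower; Mpc1 1.07, Pcx -1.11), as did mitochondrial biogenesis (8 and 8 of 27; Esrra 0.89, Esrrg -2.36), fatty acid oxidation (11 and 13 of 31; Pdk4 -2.64, Hadh -1.36), fatty acid and triglyceride synthesis (10 and 13 of 30; Dgat2 2.07, Gpd2 -1.24) and cholesterol synthesis (8 and 6 of 25; Fdft1 1.04). Adjusted over the list alone, 25 cell cycle, 8 TCA, 9 biogenesis and 14 fatty acid synthesis genes were lower. Inducible nitric oxide synthase is known to impair mitochondrial metabolism in islets and to push them towards glycolysis. The apoptosis and antioxidant lists passed camera (7.6e-14 and 3.5e-13; adjusted p = 0.0167 and 0.00217 with an estimated correlation). The ER stress (4.9e-05), immediate early (1.3e-07), glycolysis (0.0164), pentose phosphate (0.00992), nuclear and mitochondrial oxidative phosphorylation (0.0266 and 0.00273) and cell cycle lists (0.0145) passed only with the preset correlation, at adjusted p = 0.485, 0.0525, 0.657, 0.255, 0.91, 0.473 and 0.91 with an estimated correlation. The lists that went both ways did not pass (0.637 to 0.915 for these metabolic lists, 0.238 for exocytosis, 0.36 for the repressed genes and 0.63 to 0.959 for ductal, T cell, B cell, stellate and Schwann cell markers).

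In all, 5298 genes were higher and 6704 lower with cytokines in control islets at adjusted p < 0.05, 60.6% of the 19800 tested, and 2233 and 3184 of them changed at least 2-fold. Scaling sets that split. With DESeq2's size factors 6029 genes were higher and 5874 lower, so the excess of lower genes turned. TMM without acinar markers and abundant genes gave 5794 and 6142. With library totals alone the median shifts by -0.229 and the counts become 3737 higher and 8998 lower. The nuclear oxidative phosphorylation list then has a median of -0.083 instead of 0.15, the TCA list -0.138 instead of 0.09 and the repressed genes -0.186 instead of 0.04. The JAK-STAT list has 14 genes higher and 10 lower (median 0.038 instead of 0.27), and glycolysis (12 higher and 7 lower, median 0.267) and ER stress (14 and 6, 0.202) keep their direction with smaller medians. The nuclear oxidative phosphorylation counts turn to 17 higher and 23 lower and the TCA counts to 4 and 15, while the interferon, NF-kB and class I lists keep all their members higher. The direction of the oxidative phosphorylation, TCA and repressed gene medians therefore rests on the scaling.

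**Figure D2:**
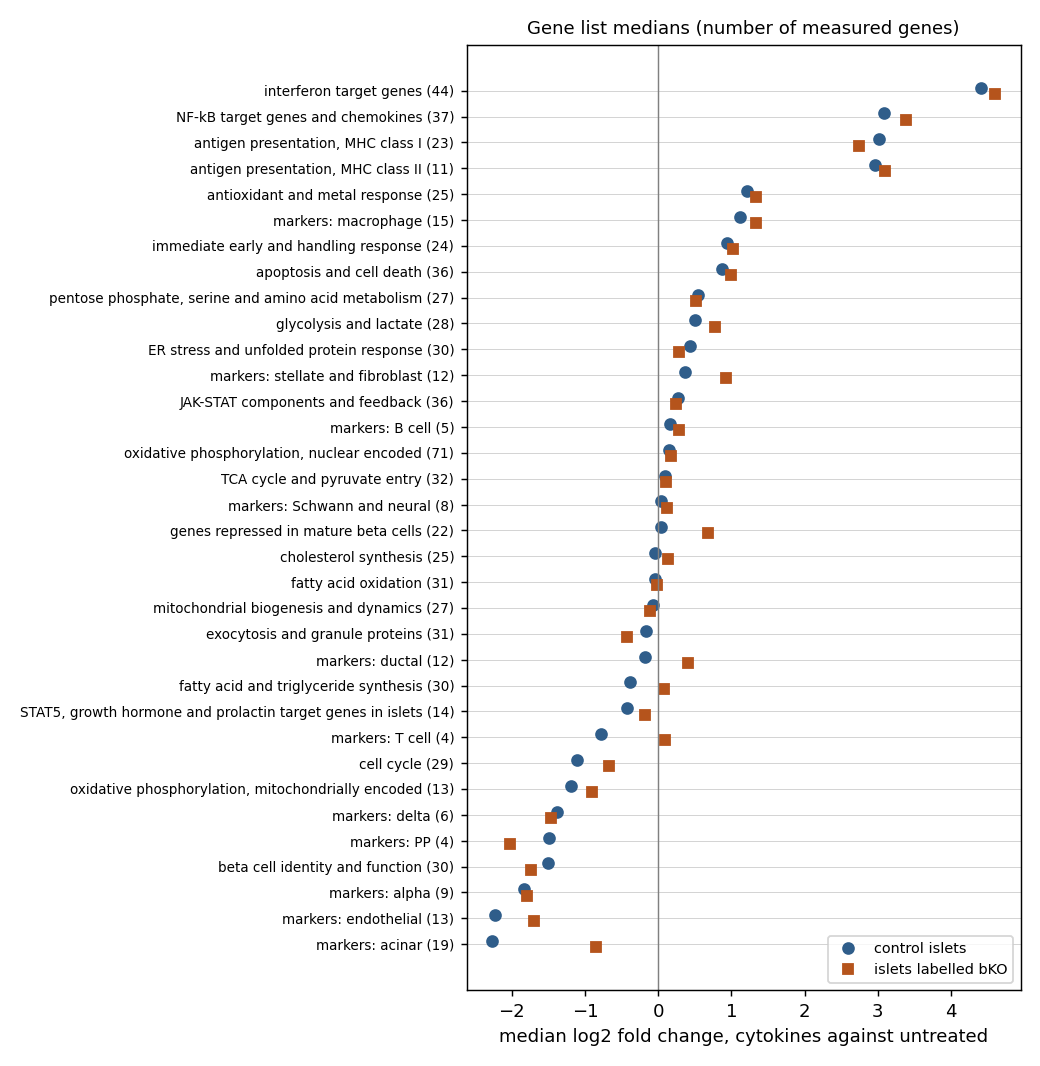
Median log2 fold change with cytokines (horizontal axis) for each gene list of at least 4 genes (vertical axis), circles for control islets and squares for islets labelled bKO. Interferon targets lie at 4.41 and 4.61 and beta cell identity genes at -1.50 and -1.74.

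Islets labelled bKO answered the cytokines much as control islets did. Cxcl9 went from 0.217 to 2490 CPM (SD 540, n = 3; log2 13.45, SE 0.50) and Nos2 from 0.288 to 1190 (SD 210; 12, SE 0.36). All 44 interferon, 37 NF-kB and 23 class I genes rose again (medians 4.61, 3.38 and 2.74), with 10 of 11 class II genes (3.10) and 17 of 36 JAK-STAT genes against 7 lower, or 13 against 13 with library totals alone (median 0.014 instead of 0.25). Pdx1 fell 7.18-fold (log2 -2.85, SE 0.11, 126 to 17.5 CPM), Ucn3 20.2-fold (-4.34, SE 0.21, 183 to 9.1 CPM) and G6pc2 8.37-fold (-3.07, SE 0.18, 910 to 109 CPM), and 26 of 30 beta cell identity genes were lower and 1 higher (median -1.74; 27 and 1 adjusted over the list alone). Ins1 (-0.10, adjusted p = 0.683), Ins2 (0.22, 0.343) and Iapp (-0.49, 0.0514) did not pass, while Gcg (-1.31, SE 0.15), Sst (-1.93) and Ppy (-1.33, SE 0.22, adjusted p = 2.3e-04) fell. In controls Ppy was at -0.50 (adjusted p = 0.0601). Slc2a1 (2.95, SE 0.16), Hif1a (1.40), Ddit3 (3.44) and Sod2 (3.38) rose and mt-Nd1 (-1.26, SE 0.14) fell. Fewer cell cycle genes fell with library totals alone, 17 of 29 against 27 in controls. With TMM and without replicate 2 of the treated islets labelled bKO, 27 of the 29 fell in both genotypes. The medians were then -1.033 in controls and -1.319 in islets labelled bKO. In that library cell cycle genes had a median deviation of 1.372 from its group (other libraries up to 0.299). The smaller count therefore does not show a different response in the other libraries. Kdr (-2.81) and 13 of 13 endothelial markers fell beside the beta cell genes, 8 of 19 acinar markers fell, and Cd68 (1.77), with 13 of 15 macrophage markers higher and 1 lower, and Dcn (2.45, SE 0.38) rose. Dcn is 1 of 12 stellate markers, of which 3 were higher and 2 lower without replicate 2 of the treated islets labelled bKO. The test called 5711 genes higher and 6647 lower, and with library totals alone 4000 and 8693. The excess turned to higher genes with DESeq2's size factors (6293 and 6023) and with TMM without acinar markers and abundant genes (6227 and 6100). The interferon, NF-kB, class I and JAK-STAT lists passed camera (1.2e-107, 6.5e-66, 3.9e-41 and 0.00111; adjusted p = 8.6e-04, 8.6e-04, 8.6e-04 and 0.0482 with an estimated correlation), and the class II and beta cell lists only with the preset correlation (1.6e-08 and 3.9e-14; adjusted p = 0.067 and 0.182 with an estimated correlation).

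Controls and islets labelled bKO shared 4568 genes higher with cytokines (1530 expected from the counts alone) and 5538 lower (2250 expected). Log2 fold changes correlated across genes (Pearson 0.895, Spearman 0.878), though genes are not independent replicates. Only 18 genes were called in opposite directions, 6 higher in controls and lower in islets labelled bKO, such as the muscarinic receptor gene Chrm3 and Tuba4a, and 12 the reverse, such as Slc39a8 and Acacb, all named after their values were seen. None of the 18 passed the direct comparison of the responses (adjusted p 0.213 to 0.314).

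Without cytokines, 15 genes were higher in islets labelled bKO than in controls and 0 were lower. The largest differences were in genes best known from the acute phase response of the liver, where IL-6 and STAT3 drive them: Fgg went from 1.75 CPM (SD 1.5, n = 3) to 111 (SD 34), 64.3-fold (log2 6.01, SE 0.64, adjusted p = 0.0019). Fga went from 0.644 CPM (SD 0.51) to 36.1 (SD 14), 57.5-fold (5.85, SE 0.57, 0.00186), and Fgb from 4.34 (SD 1.9) to 103 (SD 33), 23.9-fold (4.58, SE 0.47, 0.00186). Serpina3n, an acute phase protease inhibitor, rose 11.7-fold, from 6.67 CPM (SD 2.7) to 78.1 (SD 7.5; log2 3.54, SE 0.33), and its neighbour Serpina3i by 2.03 (SE 0.28, 0.0147), although reads of this gene family are hard to assign to single members. The prohormone gene Pomc rose 5.44-fold, from 4.33 CPM (SD 0.25) to 23.5 (SD 4.0; 2.44, SE 0.25, 0.00186), the neural adhesion gene Nrcam 2.19-fold (1.13, SE 0.12, 0.00186), Rasgrp1 by 1.36 (SE 0.17) and Mtmr10 by 0.48 (SE 0.065, 0.014). Chosen after their values were seen, the neuropeptide gene Gal (1.04, SE 0.12, 0.00417), the cytokine receptor gene Il18r1 (1.76, SE 0.19, 0.0019), Slc35f2 (3.03, SE 0.28) and Col6a4 (2.49, SE 0.25) were higher as well. Socs3, another STAT3 target, was at 0.73 (SE 0.16, adjusted p = 0.251), and Gbp8, of the STAT5 list, at 0.99 (SE 0.17, 0.0677). Interferon targets had a median difference of -0.002 (camera adjusted p = 0.48) and NF-kB targets of -0.001 (0.503), so no general interferon activation was seen, and Ins2 was at -0.06. Acinar markers had a median difference of -1.0, with no single gene passing and the list lost at adjusted p = 0.391 with an estimated correlation, and a share of the counts of 0.913% (SD 0.23) in controls and 0.403% (SD 0.098) in islets labelled bKO, which can differ with how much exocrine tissue is left on the islets. Adjusted over the list alone, 7 acinar markers were lower (Try5 -1.73, Ctrb1 -1.25), 2 class I genes higher (Tap2 0.30, Nlrc5 0.67) and 2 STAT5 targets higher. With the preset correlation camera called 7 of 34 lists: the acinar (1.1e-19), mitochondrially encoded (median -0.30, 1.5e-08), beta cell identity (-0.09, 0.0295) and glycolysis lists (-0.12, 0.0295) lower, and the class I (0.08, 1.3e-04), ER stress (0.12, 1.6e-04) and cell cycle lists (0.20, 0.0349) higher. None held, at adjusted p = 0.391 for the acinar, mitochondrial and class I lists and adjusted p = 0.861 for the other 4 with an estimated correlation. The calls of these 4 also ended when some single libraries were left out. The 10 splits of 6 libraries are too few for a share under 0.05: the real split called 15 genes and the highest other 0. Leaving out 1 library gave 12 to 17 calls, except 59 without replicate 2 of the treated islets labelled bKO, which is in neither compared group. All groups share the estimate of the spread. Libraries deviated from their group means with an SD of 0.232 to 0.281 log2 in untreated and 0.276 to 0.464 in treated islets. A fit of the compared groups only called more than 15 genes. The numbers of calls without and with cytokines therefore do not rank the size of the genotype difference. Groups of 3 and 3 libraries without overlap arise by chance in 10% of genes.

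**Figure D3:**
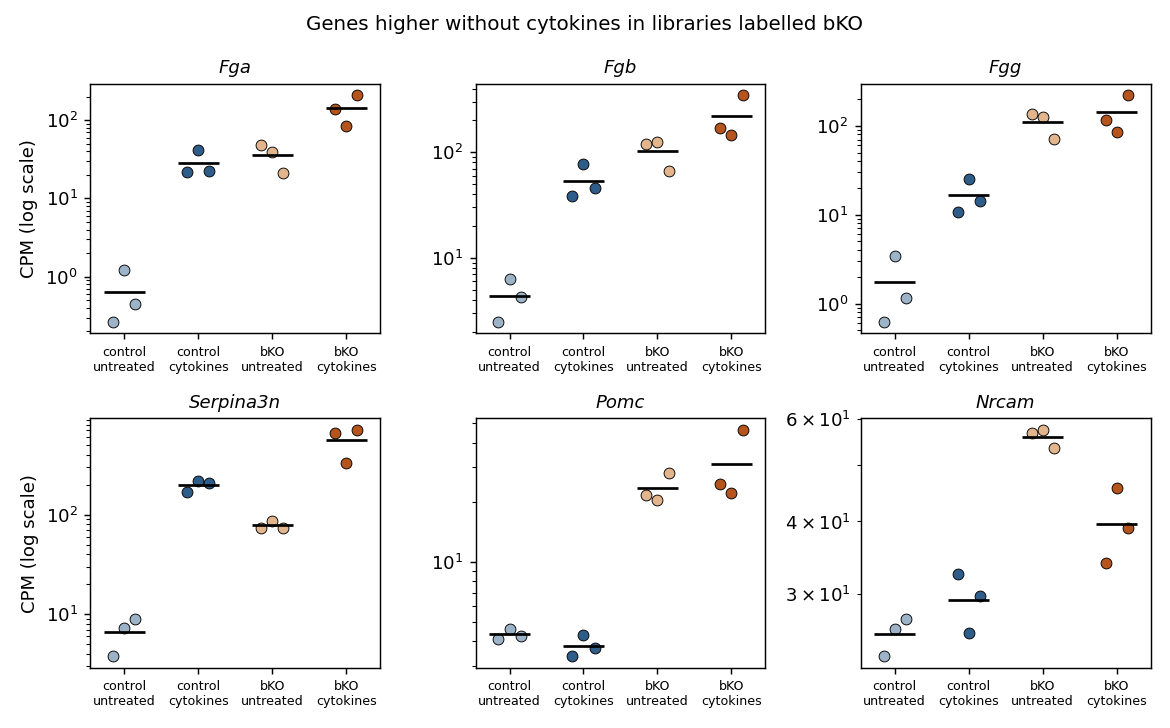
Levels in CPM (vertical axis, log scale) of Fga, Fgb, Fgg, Serpina3n, Pomc and Nrcam in the 4 groups (horizontal axis). Points are libraries and lines the mean of 3, for untreated Fgg 1.75 in control and 111 in labelled-bKO islets.

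With cytokines, 28 genes were higher and 18 lower in islets labelled bKO than in controls. Pomc was again higher, 3.79 CPM (SD 0.49, n = 3) against 31.3 (SD 13), 8.23-fold (log2 3.04, SE 0.26, adjusted p = 0.00171), as were Fgg (3.06, SE 0.54, 0.0496), Slc35f2 (2.21, SE 0.27) and Col6a4 (2.14). These 4 are the genes called in both conditions, where 0.0212 would be shared by chance if the 2 comparisons were independent. Libraries of both treatments can come from the same mice, and both comparisons use the same estimate of the spread, so the overlap is not independent replication. Fga (2.34, 0.0651), Fgb (2.04, 0.0698) and Serpina3n (1.52, 0.0698) did not pass. The mature beta cell gene Ucn3 was 2.33-fold lower (-1.22, SE 0.19, adjusted p = 0.0334; 21.1 CPM, SD 3.3, against 9.1, SD 2.5), and G6pc2, a glucose phosphatase gene of beta cells that restrains glycolytic flux, 2.11-fold lower (-1.08, SE 0.17, 0.0334; 229 CPM, SD 24, against 109, SD 24). Chrm3, the receptor through which acetylcholine increases insulin release, was also lower (-0.92, SE 0.16, 0.0405), with the meiotic gene Rec8 (-1.12, SE 0.11, 0.00573), Robo1 (-0.70) and AW112010 (-0.78, SE 0.082, 0.00613; 136 against 79.1 CPM). The substance P gene Tac1 (1.40, SE 0.20, 0.0297) and the interferon-induced gene Cxcl11 (0.69, SE 0.11, 0.0355; 29.4 against 47.4 CPM) were higher, as were, chosen after their values were seen, Npy (1.05, SE 0.16, 0.0334) and the alarmin gene Il33 (1.15, SE 0.19, 0.0405). Loss of a JAK-STAT phosphatase, which the Ptpn2 counts here do not show, could raise interferon targets. Cytokines had already raised these targets in controls, so the values that follow do not decide whether Ptpn2 was lost. Cxcl10 was at 0.03 (0.93), Nos2 at 0.05 (0.923), Irf9 at -0.58 (0.0682) and Cd274 at -0.40 (0.0918). Cxcl11 was the only 1 of the 44 targets to pass, and adjusted over the list alone 3 were higher and 7 lower (median -0.09). Of 30 beta cell identity genes 2 were lower, and 20 lower and 1 higher adjusted over the list alone (median -0.50; Gipr -0.86, 0.0813; Trpm5 -1.03, 0.0826), beside ductal (median 0.45) and stellate cell markers (0.68), whose single genes did not pass over all genes, with 2 ductal and 0 stellate markers higher adjusted over the list alone. Without replicate 2 of the treated islets labelled bKO these medians were -0.326, 0.151 and 0.000. Camera called the beta cell list (1.2e-17; adjusted p = 0.733 with an estimated correlation) and 15 other lists, and 0 of the 16 held. The real split of the 6 libraries called more genes than the other 9, whose highest was 0, but 10 splits are too few for a share under 0.05. Leaving out 1 library gave 444 calls without replicate 1 and 69 without replicate 2 of the treated islets labelled bKO, and 4 to 15 without any of the other 10. The call of Ucn3 and of G6pc2 was lost in 10 of 12 fits that each left out 1 library. Cxcl11, Chrm3 and Npy kept theirs in 2 of these fits, Fgg and Robo1 in 3, Il33 in 1 and Tac1 in 5. Only 3 genes, Pomc, Rec8 and AW112010, kept theirs in all 12. With only the 2 compared groups in the fit edgeR called 0 genes, these 3 included, so the calls lean on the spread estimated from all 12 libraries.

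**Figure D4:**
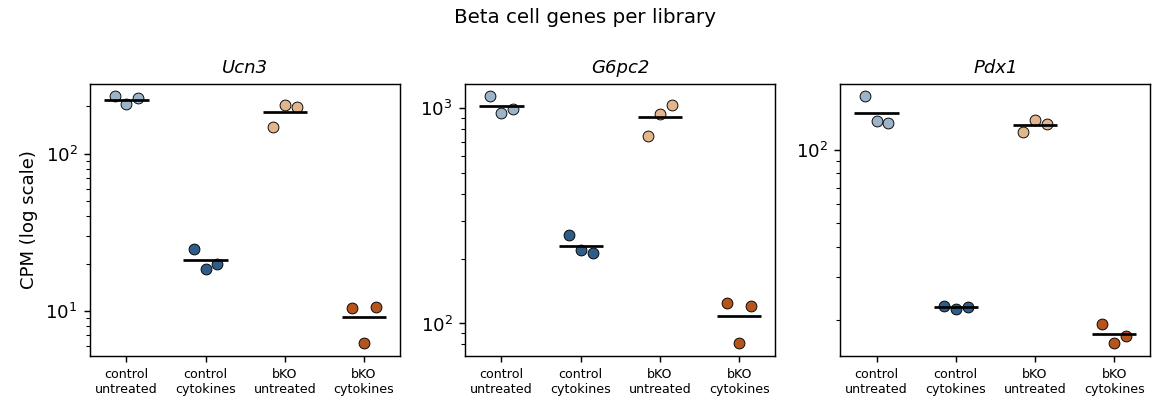
Levels in CPM (vertical axis, log scale) of Ucn3, G6pc2 and Pdx1 in the 4 groups (horizontal axis). Points are libraries and lines the mean of 3, for treated Ucn3 21.1 in control and 9.1 in labelled-bKO islets.

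The differences between genotypes with and without cytokines hardly correlated across genes (Pearson 0.0395, Spearman 0.0235). Of the 15 genes called without cytokines, 14 had the same sign with them, 13 of these at unadjusted p < 0.05. Of the 46 called with cytokines 36 had the same sign without, 19 at unadjusted p < 0.05. Libraries of both treatments can come from the same mice, so these counts are not independent replication. No gene passed as responding differently to cytokines between the genotypes: edgeR called 0 (smallest adjusted p = 0.213, 2162 genes at unadjusted p < 0.05), limma-voom 0 and DESeq2 186. Among the nearest were Apol7a (2.46) and Mapk13 (1.19), with a larger response in islets labelled bKO, and Gbp8 (-1.46, SE 0.23) and Serpina3i (-2.07), with a smaller one, all at 0.213. G6pc2 was at -0.90 (0.298). The fibrinogen genes, already high in untreated islets labelled bKO, were at -3.51 for Fga (0.246), -2.54 for Fgb (0.251) and -2.94 for Fgg (0.296). A 2-fold change planted in simulated counts was found in 50.7% of genes for this comparison and a 1.5-fold change in 4.55%, so smaller differences in response would mostly be missed.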

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

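The comparison of responses and the splits of the libraries were planned, and the 3 tests on replicate 2 of the treated islets labelled bKO were chosen only after the result was seen. Of the lists compared for a different cytokine response between genotypes, 11 passed camera with its preset correlation, and none of the 11 held with an estimated correlation (adjusted p 0.584 to 0.756). Relative to controls and with the preset correlation, the response of islets labelled bKO was lower in beta cell identity (median difference in log2 fold change -0.403, adjusted p = 6.2e-08), exocytosis (-0.302, 1.7e-05), class I (-0.174, 0.00163) and ER stress genes (-0.112, 0.00805). It was higher in genes repressed in mature beta cells or active in progenitors (0.498, 0.00116), glycolysis (0.328, 0.00133), mitochondrially encoded (0.29, 9.6e-04) and fatty acid and triglyceride synthesis genes (0.156, 0.0374). Markers of acinar (1.531, 1.3e-11), ductal (0.476, 9.4e-04) and endothelial cells (0.316, 0.00227) were higher as well. Acinar genes took 0.913% of counts in untreated and 0.156% in treated controls, and 0.403% and 0.224% in islets labelled bKO. Without replicate 2 of the treated islets labelled bKO the differences were -0.21 for beta cell identity, -0.143 for exocytosis, 0.199 for the repressed genes and 0.17 for ductal markers. The calls of ER stress (-0.06, 0.317) and fatty acid synthesis (-0.013, 0.254) ended without it. Those 2 calls also ended without replicate 3 of the untreated islets labelled bKO or replicate 2 of the treated controls, ER stress without replicate 2 of the untreated controls, and fatty acid synthesis without replicate 1 of either control group. The endothelial call ended without replicate 3 of the treated islets labelled bKO (0.0534). No single gene passed in edgeR (2162 at unadjusted p < 0.05; DESeq2 186, limma-voom 0).

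For this comparison any of the 100 drawn reassignments of genotype within treatment, the real one included, reaches the real 0, so their number decides nothing. The 6 that called any gene all keep the 3 untreated libraries labelled bKO together. The highest, 53, exchanges the genotype labels of all treated libraries, so that the genotype differences of both treatments add up in it. For the other comparisons, 10 splits are too few for a share under 0.05, and only the real 1 reached its own value. The real values and highest others were 12002 and 1 for cytokines in controls, 12358 and 0 for cytokines in islets labelled bKO, 15 and 0 for genotype without cytokines, and 46 and 0 for genotype with cytokines. Every other split for cytokines mixes treated and untreated libraries in both groups, which widens the spread. Few calls there were therefore fixed in advance, and nothing is concluded from them.

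Replicate 2 of the treated islets labelled bKO stood apart. It lay at -42.3 on the second principal component (others -10.7 to 21.3), had 8.15% of its counts in Ins1 and Ins2, and differed from the mean of its group's other libraries with an SD of 0.696 log2 (others 0.349 to 0.531). Its deviations did not track exon length more than elsewhere (Spearman 0.16; another library 0.33), and across genes they were unrelated to the cytokine response (correlation 0.012), which argues against a length bias and against a response stronger in all genes. On the first component, which separates treated libraries, it lay furthest out (78.6, other treated libraries 63.6 to 70.2), with beta cell identity genes at -0.754 and interferon targets at 0.045, so a stronger loss of beta cell transcripts alone stays open. A candidate explanation is more RNA from ductal and stellate cells: ductal markers had a median deviation of 0.845 (other libraries up to 0.331) and stellate markers of 1.243 (up to 0.815), above every other marker list (B cell markers came next at 0.794). Acinar markers moved the other way, at -1.347 (other libraries -0.652 and above) and 0.0981% of the counts, so exocrine RNA as a whole was not higher. Fn1 was at 1610 CPM there, against 419 and 420 in replicates 1 and 3, Col3a1 at 1880 against 830 and 815, and Epcam at 758 against 508 and 557, but islets express several of these genes, Sox9 and Pdgfra stand also in the list of repressed genes, and cell cycle genes deviated too (1.372). Without this library the genotype difference of the beta cell list with cytokines was -0.326 instead of -0.50 and that of stellate markers 0.000 instead of 0.68. A difference in the islets of that mouse stays open and was not tested.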

How the results depend on the processing

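No test in this part was chosen after the result was seen. Under cytokines, the called genes stayed within 1.5 times under every setting except a 2-fold minimum (5417 genes in controls, 5755 in islets labelled bKO), and leaving out each library gave 10846 to 13164 and 11050 to 12634. The 15 genes of genotype without cytokines became 32 (29 higher, 3 lower) with no filter, 128 (92 and 36) with DESeq2 and 121 (91 and 30) with only the compared groups, and 12 to 59 leaving out each library. The 46 with cytokines became 190 (63 and 127) with no filter, 705 (296 and 409) with DESeq2, of which 44 are shared, 0 with only the compared groups, 7 with the replicate block, 7 at adjusted p under 0.01 and 25 at 2-fold or more. Leaving out each library gave 4 to 444, so this count depends on which libraries enter. Each such fit also repeats the gene filter and the estimate of the spread, and these effects are not told apart from that of the library. Leaving out an untreated library, which is in neither compared group, kept 8 to 14 of the 46 calls. The difference in response gave 1 gene with no filter, 186 with DESeq2, and 0 to 3 leaving out each library (3 without replicate 3 of the untreated islets labelled bKO, 1 without replicate 2 of the untreated controls). The Ptpn2 difference was never past the threshold in these leave-outs, at 0.159 to 0.219 without cytokines and 0.155 to 0.325 with them. The correlation of the responses was 0.549 with no filter, 0.943 with the 1 CPM filter, 0.725 in the filtered table and 0.835 to 0.881 leaving out each library. Of the 16 lists camera called between genotypes with cytokines, 2 changed direction when a library was left out: nuclear oxidative phosphorylation without replicate 3 of the treated controls (camera adjusted p = 0.977, and 1.4e-04 to 0.977 over the leave-outs), and cell cycle without replicate 2 of the treated islets labelled bKO (0.968, and 5.7e-09 to 0.968). With fry, all 21 and 20 lists that camera called for cytokines in controls and in islets labelled bKO stayed called. None did of the 7 and 16 lists called for genotype without and with cytokines, or of the 11 for the difference in response. Libraries with the same replicate number did not deviate together, with correlations of -0.10 to 0.10 between treated and untreated libraries and -0.49 to 0.02 between genotypes, so the numbers were not used as pairs in the main tests. Between treated libraries of different genotype and number the correlations were -0.28 to 0.40, so libraries with other numbers can deviate together. Some libraries of a genotype must share mice, and which ones is not given, so the main tests do not account for it. The replicate block gave 11347 and 11634 genes for cytokines, 12 for genotype without cytokines and 0 for the difference in response. A batch covariate was not run, since the sample table names no batch, nor a sex covariate, since all 12 libraries carry Y-linked and almost no Xist counts.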

Other observations

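The 3 tests on the fibrinogen and Serpina3 genes and on neighbouring genes, and the neuropeptide genes named here, were chosen only after the result was seen. Neuropeptide genes are given here one by one, with no test of them as a group, and 60.6% and 62.4% of all tested genes changed with cytokines in control and labelled-bKO islets. Tac1 went from 0.263 to 14.2 CPM with cytokines in control islets (log2 5.78, SE 0.27, adjusted p = 1.3e-08, edgeR) and from 0.433 to 37.6 in islets labelled bKO (6.43). Gal went from 1.15 to 17.2 CPM (3.90, SE 0.12, 7.1e-10) and from 2.35 to 22.6 (3.26), and Nts rose by 2.25 and 2.30. Vip (0.59, 0.00285) and Penk (0.97, 0.0275) rose less in controls. Pomc did not pass with cytokines, at -0.19 (0.533) in controls and 0.41 (0.145) in islets labelled bKO, but its level followed the genotype label, at 4.33 and 3.79 CPM in untreated and treated controls and 23.5 and 31.3 in islets labelled bKO. Npy (5.21, 3.41, 8.11 and 7.07 CPM in the same order) and Cartpt (4.20, 2.71, 8.02 and 8.19) had genotype differences of 0.64 (adjusted p = 0.284) and 0.93 (0.592) without cytokines and 1.05 (0.0334) and 1.58 (0.0681) with them. The call of Npy stayed in 2 of 12 fits that left out 1 library. Substance P and galanin act on islet hormone release and on immune cells, and their source cell is not given by bulk RNA.

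Control islets also raised the fibrinogen genes once cytokines were added: Fga by 5.51, Fgb by 3.64, Fgg by 3.29 and Serpina3n by 4.88 (log2). In islets labelled bKO, already high, Fga rose by 2.00, Fgb by 1.10 and Serpina3n by 2.86, and Fgg was at 0.35 (adjusted p = 0.553). The untreated islets labelled bKO thus stood at 103 CPM of Fgb, above the 53.8 of treated controls, but at 78.1 of Serpina3n, below their 198, while Cxcl10 (-0.06) and Nos2 (-0.12) did not pass between genotypes.

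RNA from liver cells was weighed as a source of the 5 fibrinogen and Serpina3 genes. Alb, the most abundant liver transcript, was at 0.417 CPM in untreated islets labelled bKO and 0.877 in controls, far under Fgb at 103, and none of the 7 tested of 13 liver markers was called (0 in edgeR), which argues against it. A single library was not the cause, since at least 4 of the 5 genes stayed called with any of the 12 left out. These genes differed with the genotype label, as tested above. Loss of Ptpn2 cannot be told apart here from other differences between the mice that carry the labels. Socs3, like these genes a STAT3 target, was at 0.73 (adjusted p = 0.251).

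The mice have a mixed C57BL/6J background, so genes near the modified locus or near other strain variants could differ by descent. Of 57 genes called between genotypes in either condition (54 with each family counted once), 9 pairs of different families lay within 5 Mb of each other. Among 10000 random draws of as many genes, the average was 8.71 and the 95th percentile 14, and a share of 0.48 had at least as many. Neighbours of different families were thus no more frequent than chance. The count cannot register Fga, Fgb and Fgg, or Serpina3n and Serpina3i, as neighbours, since relatives lying together were counted once. Distance to Ptpn2 itself was not measured, so the count does not test genes near the modified locus. Single pairs stay open, such as Fgg and Tmem131l, 0.89 Mb apart on chromosome 3, and Trpm1 and Mtmr10, 0.134 Mb apart on chromosome 7.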
